A study of Bacillus subtilis subsp. subtilis str. 168 with 6 samples.

How the data were processed

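Total RNA from cultures of Bacillus subtilis strain GP193 was measured on 6 two-colour Agilent oligonucleotide arrays, which carried 3 biological replicates (A, B and C). In this strain rny, the gene of the endoribonuclease RNase Y, is read from a promoter that needs xylose. On each array the culture grown without xylose, depleted of RNase Y, was set against the culture grown with xylose, which expressed it. Each replicate was hybridised with the dyes one way and then the other way, per the labels. Per the labels' protocols, 10 µg of total RNA was mixed with the spike-in RNAs of a commercial kit and copied from random primers into cDNA that carried Cy3 or Cy5. Absence of xylose and depletion of RNase Y went together in every sample, so an effect of the sugar itself cannot be told apart from an effect of RNase Y by this design.

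The deposited scanner files give the mean spot intensity and the median local background intensity of each spot in both channels. Per the file headers these came from Agilent Feature Extraction version 10.2.1.3, whereas the submitters' processing notes name version 10.5. The files also hold Feature Extraction's processed intensities, which per the file headers are background-subtracted, spatially detrended and dye-normalised with a linear and a LOWESS step. They further hold a log10 ratio of processed red over processed green, as deposited by the authors. Flags for spots well above background, saturated spots and outlier spots were used as deposited. The authors' deposited table of processed values for the series has 41882 rows whose numbers match no probe column. Set against the arrays' own values, its columns equal the scanner's log10 ratios, to 3 significant digits, turned to xylose over no xylose, with column medians between -0.00977 and 0.00287. Of these rows, 41537 match the values of 1 probe and 345 match several, and the table was not used for any result.

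Each array held 43457 spots. Of these, 42040 were no controls. They comprised 21197 probes for 4105 genes, 20660 probes for both strands of the regions between genes and 105 probes for predicted features. The other 78 probes were for genes listed without a locus tag, such as resistance markers and reporters. The probes were 55 to 60 bases long, and the median gene had 6. Gene symbols were taken through the locus tag from the RefSeq table of assembly ASM904v1, which held 4037 of the 4105 genes and changed 1028 names, and rny is listed on the array as ymdA. The same table gave which genes neighbour each other, and none of its coordinates are printed. Probe coordinates are those of the scanner files, whose genome build is not given in the sources used here, on the single chromosome of the strain. The description of 41 gene probes names a similar site elsewhere.

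Background was corrected with normexp (offset 50), and ratios were normalised within each array by loess fitted to gene probes without outlier spots, with limma 3.58.1 and statmod 1.5.0 in R 4.3.3. All ratios were turned to depleted over expressing, and outlier spots were left out. A probe was kept when it was well above background on at least 4 of the 6 arrays in 1 culture or both. The value of a gene on an array was the median of its probes, which could differ along a gene as reported for those tested. The dye-swapped arrays of a replicate were averaged to 1 value, so that n = 3 log2 ratios entered each test. No saturated spot was removed. No gene lacked a probe well above background in 1 culture on all 6 arrays while having one in the other, so no change had to be given as a bound.

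Each gene was tested with limma (lmFit on an intercept, eBayes, two-sided) and Benjamini-Hochberg adjustment over 4100 genes, and all adjusted p-values come from limma. Genes called at adjusted p under 0.05 were also counted at a change of at least 2-fold. A total of 27 gene lists, among them markers of competent and sporulating cells, were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry. Unequal change along a gene was tested with diffSplice and Simes' method over 3781 genes of at least 3 probes, and unequal change of neighbours over 1923 pairs on 1 strand at most 100 bases apart. Features outside genes were tested like genes, over 4223 features. The depth of an array is not a count: 98.8% to 99.9% of gene probes were well above background in the depleted culture on 5 arrays and 92.1% on the remaining one, and the number of replicates limits the precision.

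The files do not say which spike-in RNAs were added in equal amounts, so the planned use of those alone was replaced. Their red over green ratios had the same pattern on every array (lowest correlation across the 10 spike-in RNAs between arrays 0.993), so the ratios followed the dye. The mean over the dye swap removes such a ratio, and the median over all 10 was used instead, a choice made after the data had been examined.

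The lists, the tests of the comparisons, most alternatives and the rule for named genes were fixed before the data were examined. Further alternatives and tests, named as such where their values are given, were added later. The rule took rny, the 12 largest rises and 12 largest falls among called genes that moved 1 way on all 6 arrays with a probe well above background in both cultures on all 6, up to 3 genes each way that were well above background in 1 culture only (there were 0), up to 4 members of each list with the lowest p, the 6 genes with the lowest Simes p, and the 6 neighbouring pairs with the largest difference. Genes or features named outside it were chosen after their values were seen, as stated where they are named. The pairing of cultures comes from the design, in which both cultures of a replicate lie on the same arrays. Deviations of the separate channels from the culture means correlated across genes at 0.0206 for A, 0.441 for B and 0.53 for C. The depleted culture of A correlated more with the expressing culture of B (0.12) than with that of A. Both channels of a replicate come from the same spots, whose shared brightness can raise such a correlation however the cultures were paired. These values therefore do not test the pairing, which rests on the shared arrays alone in A, B and C. Alternatives covered background correction, normalisation, filters, probe summaries, leaving out each replicate, arrays of 1 dye orientation, models over 6 arrays with the replicate or the slide as a random block, an unpaired fit, list tests and thresholds. Slide 1 held replicates A and B, and slide 2 held replicate C.

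The steps were tested on simulated data for this comparison, with 4100 genes and the spread of the 3 replicates. With no change simulated, 0 genes, 0 of 27 lists and 0 of 1920 simulated pairs were called. The simulated genes varied independently, so these counts do not test lists or pairs whose members vary together. In the data the estimated correlation within a list was 0.987 for the respiration genes and 0.978 for the S-box genes. Of 200 changed genes, 77% of 2-fold and 89% of 4-fold changes were recovered, with median fitted log2 sizes of 0.99 and 2.01, and 14 unchanged genes were called as well. Among 100 genes with 1 probe shifted 4-fold upwards, 91% were recovered. Smaller shifts of 1 probe were not simulated.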

Results

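The transcriptomes of Bacillus subtilis GP193 cells depleted of RNase Y, an essential endoribonuclease that starts the decay of many mRNAs, and of cells expressing it were compared on 6 two-colour arrays. The question was which RNAs depend on this enzyme. Cells grew in a minimal medium at 37 °C without or with xylose, the inducer of rny in this strain, and per the labels were harvested when the culture without xylose first showed a change of growth rate. There were 3 biological replicates, each a pair of cultures on 2 arrays with swapped dyes. Of the gene probes, 97.9% to 99.8% were well above background in the expressing culture on 5 arrays, and 89.4% on the array of replicate C with the depleted culture in Cy3. All values are log2 ratios of depleted over expressing culture, relative to the median gene, with the SD over n = 3 replicates.

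The rny transcript (listed as ymdA, BSU16960) was 12.3-fold lower in the depleted cultures, with a log2 ratio of -3.63 ± 0.17 (SD, n = 3, adjusted p = 0.00551). Its ratios on the arrays were -3.52 and -3.80 in replicate A, -3.60 and -3.95 in B, and -3.27 and -3.61 in C. Its probes span positions 1766551 to 1768022 on the plus strand of the chromosome, in a build the files do not name. Probes just upstream of the gene, between 1766412 and 1766565, were at 0.74 to 0.82. The 5 probes inside the gene ranged from -3.50 to -3.98, while the probe across the start codon, at 1766551 to 1766606, had a ratio of 0.52 ± 0.21 and was the brightest of the gene. With this brightest probe alone, the rny value turned to 0.52, and without replicate B the value was -3.55 at an adjusted p of 0.0838. The next gene on the same strand, pdeB (ymdB, BSU16970), fell by 2.48 ± 0.42 (adjusted p = 0.0206). Both genes fell in all 3 replicates, so effects of less pdeB cannot be told apart from effects of less rny. The 4 members of the XylR regulon, which is switched on by xylose, all fell, and over the list alone all 4 passed as well. The xylose isomerase gene xylA was 97.9-fold lower (-6.61 ± 0.21, adjusted p = 0.00258), the xylulokinase gene xylB 39.9-fold (-5.32 ± 0.29), the xyloside transporter gene xynP 26.5-fold (-4.73 ± 0.47) and the xylosidase gene xynB 9.35-fold (-3.23 ± 0.43). The list's median was -5.02 (camera, adjusted p = 1.9e-05, and adjusted p = 0.843 with an estimated correlation). In camera with an estimated correlation 0.843 was the lowest adjusted p of all 27 lists. That setting thus called 0 lists, the XylR regulon included.

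Depletion went with a rise of 488 genes and a fall of 254 of the 4100 tested at adjusted p under 0.05, led by the tryptophan genes among the rises and by the xylose and exopolysaccharide genes among the falls. Changes of at least 2-fold made up 95 rises and 73 falls. The median gene lay 0.74 above the spike-in RNAs in replicate A, 0.36 in B and 0.31 in C, a mean shift of 0.47 ± 0.23 (SD, n = 3) or 1.39-fold. An exact sign-flip test (two-sided) gave p = 0.25, the smallest that 3 replicates allow. With ratios centred on the spike-in RNAs, the same data gave 1617 rises and 83 falls, 95.1% rises against 65.8%, and the median of all genes moved up by 0.48. Directions given here are therefore relative to the median gene. The SD of the log2 ratios over genes was 0.87 in A, 0.45 in B and 0.54 in C. Without replicate A there were 768 rises and 660 falls, 53.8% rises. With limma there were 0 rises and 1 fall without B, and 0 rises and 4 falls without C, which leaves slide 1 alone. At an unadjusted p under 0.05, 946 genes passed without B and 924 without C, against 1570 with all replicates. Of the named genes, pairs, lists and genes of unequal probes called with all replicates, 107 were also called without A and 3 were not. Both without B and without C, 20 were also called and 90 were not. Without B limma called 1 gene and 0 pairs in all, and without C 4 genes and 0 pairs. Most of the 20 were therefore lists or genes of unequal probes. On slide 2, which held C alone and allows no test, 118 genes were at least 2-fold higher and 145 at least 2-fold lower. With the slide as a random block over the 6 arrays, 894 genes rose and 738 fell. That fit leaves out the replicate, so the swapped arrays of 1 culture pair count as separate units. With the replicate block as random 683 rose and 509 fell. Separate channels of 3 against 3 cultures with no replicate block gave 351 rises and 182 falls.

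The 12 largest rises came mainly from 2 clusters of adjacent genes. In the operon for tryptophan synthesis, trpE rose 10.0-fold (3.32 ± 1.16, adjusted p = 0.033), trpD by 3.27 ± 1.21, trpC by 3.21 ± 1.22, trpF by 3.10 ± 1.28 and trpB by 2.94 ± 1.20. The ratio of trpE was 4.45 in replicate A, 3.38 in B and 2.14 in C. Further along the operon trpA, named after its value was seen, rose by 1.496 ± 0.61, although its probes did not share 1 level. Those nearest trpB were at 2.745 and 2.796, and the rest lay between 1.229 and 1.415. The test for unequal change along a gene did not call trpA. A spread between replicates that all probes of a gene share enters the error of that test. In a cluster between positions 975877 and 979643 on the plus strand, yhcA rose 6.71-fold (2.75 ± 0.25, adjusted p = 0.0127), yhbJ by 2.74 ± 0.21, yhbI by 2.72 ± 0.25, yhcB by 2.58 ± 0.17 and yhcC by 2.16 ± 0.19. The gene of malic enzyme, maeA, rose 3.41-fold (1.77 ± 0.57, adjusted p = 0.0307), and ynfCn rose 3.35-fold (1.74 ± 0.10, adjusted p = 0.0127). All of these were higher in 6 of 6 arrays, and they also rose with spike-in centring.

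**Figure D1:**
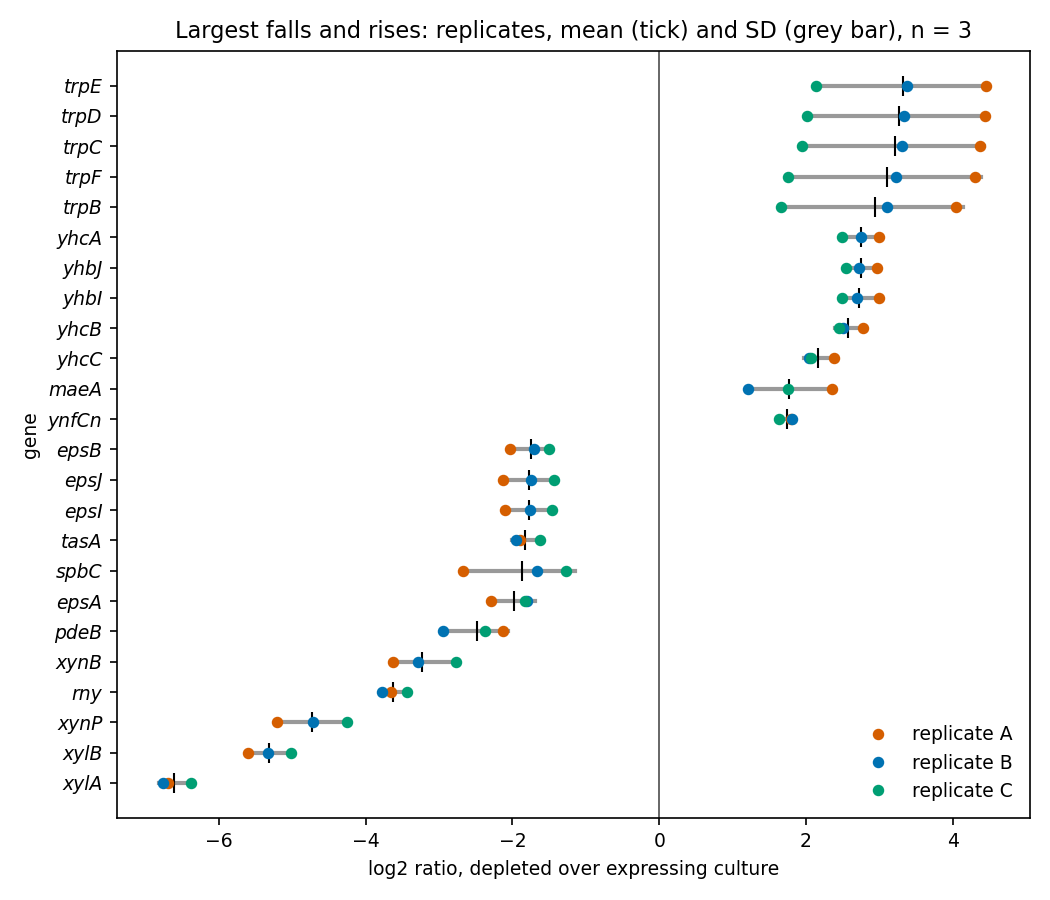
Log2 ratio of depleted over expressing culture (x axis) for the 12 largest falls and 12 largest rises (y axis, 1 gene per line). Points are the 3 replicates, black ticks the mean and grey bars the SD, and the replicates of trpE spread from 2.14 to 4.45 while those of yhcA lie between 2.49 and 2.998.

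After the xylose genes, rny and pdeB, the largest falls were in genes for the biofilm matrix. The exopolysaccharide genes epsA (-1.97 ± 0.28, adjusted p = 0.0206), epsI (-1.77 ± 0.32), epsJ (BSU34280, -1.77 ± 0.35) and epsB (-1.75 ± 0.26) fell, as did tasA for the matrix fibre, 3.54-fold (-1.82 ± 0.18, adjusted p = 0.019). The toxin gene spbC fell 3.66-fold (-1.87 ± 0.72, adjusted p = 0.0377). All fell on 6 of 6 arrays, and also with spike-in centring. Whether these falls go with the loss of rny, of pdeB or of xylose cannot be told apart by this design. The same holds for the change of growth rate in the culture without xylose, at which cells were harvested.

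Of the 27 matrix genes tested, 19 fell and 2 rose (19 and 3 adjusted over the list alone), with a median of -1.35. The shift passed camera at an adjusted p of 1.02e-06 (adjusted p = 0.843 with an estimated correlation), and the median remained below 0 with spike-in centring, at -0.87. Besides the genes above, epsF (-1.57 ± 0.23) and slrR for a regulator of matrix genes (-1.31 ± 0.17) fell, while remA, which encodes an activator of matrix genes, rose by 0.98 and slrC by 0.33, both named after their values were seen. Of 156 genes of the prophage SPbeta, 94 rose and 1 fell (116 and 4 adjusted over the list alone), with a median of 0.59 (camera, adjusted p = 3.21e-18, and adjusted p = 0.843 with an estimated correlation). Examples are hupN for an HU-like protein (1.29 ± 0.19, adjusted p = 0.0206), yosQ (1.12 ± 0.15) and yotH (0.86 ± 0.08). Of 31 genes of the defective prophage PBSX, 0 rose and 12 fell (0 and 27 adjusted over the list alone), with a median of -0.98 (camera, adjusted p = 2.9e-09, and adjusted p = 0.843 with an estimated correlation). Among them were xkdN (-1.15 ± 0.48, adjusted p = 0.0428) and xkdM (-1.13 ± 0.51). With spike-in centring 0 PBSX genes passed, at a median of -0.51.

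Genes read through tRNA-sensing T-box leaders lay lower than other genes, with a median of -0.46 over 27 genes, 11 falls and 2 rises (16 and 2 adjusted over the list alone). Camera gave an adjusted p of 1.9e-05 (adjusted p = 0.843 with an estimated correlation), and with spike-in centring the median turned to 0.02. The leucine synthesis genes leuD (-0.82 ± 0.12, adjusted p = 0.0235) and leuB (-0.66 ± 0.13) and the glycyl-tRNA synthetase genes glyS (-0.57 ± 0.10) and glyQ (-0.53 ± 0.06) fell, while pheS (1.01) and pheT (0.9955), for phenylalanyl-tRNA synthetase and named after their values were seen, rose. In the list of tryptophan and histidine synthesis, 6 genes rose and 7 fell of 21 (9 and 8 adjusted over the list alone). The 6 rises were trpE to trpA, and the falls were his genes such as hisIE (-0.61 ± 0.12, adjusted p = 0.0298), hisF (-0.62 ± 0.13) and hisG (-0.51 ± 0.07). The value of hisG was below 0 on 3 of 6 arrays and was 0.29 on the arrays with the depleted culture in Cy3 alone, while hisIE and hisF were lower on 6 of 6. The median was 0.23 (-0.05 without replicate A) and the list did not pass (camera, adjusted p = 0.824). With spike-in centring 10 of its genes rose and 0 fell, at a median of 0.71, with hisIE and hisF at -0.14 and hisG at -0.036. Among 33 genes behind other riboswitches, 3 rose and 5 fell (4 and 12 adjusted over the list alone). Their median was 0.02, their mean -0.25 and camera's direction down (adjusted p = 0.23, and adjusted p = 0.0416 without replicate B). The riboflavin uptake gene fmnP behind an FMN riboswitch rose 2.54-fold (1.35 ± 0.18, adjusted p = 0.0206), while thiU (-1.32 ± 0.44, adjusted p = 0.0331), thiV (-1.31 ± 0.46) and thiW (-1.20 ± 0.44) behind a thiamine pyrophosphate riboswitch fell.

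Of 38 genes for the cell wall and cell shape, 8 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.08 (camera, adjusted p = 0.0248, adjusted p = 0.843 with an estimated correlation, and adjusted p = 0.0678 without replicate B). It was also lost on arrays of 1 dye orientation, with adjusted p = 0.0637 for the depleted culture in Cy5 and 0.0607 in Cy3. The penicillin-binding protein gene pbpA rose 2.56-fold (1.36 ± 0.20, adjusted p = 0.0206), and the teichoic acid genes tagA (0.82 ± 0.09), tagO (0.75 ± 0.02) and tagD (0.64 ± 0.02) rose. Among 21 genes for RNA decay and processing, ricT (0.80 ± 0.10, adjusted p = 0.0225) and ricF (0.64 ± 0.08), whose products are partners of RNase Y, rose, 0 fell and the list did not pass (median -0.05 and 0.43 with spike-in centring, mean 0.01, camera direction down, adjusted p = 0.919, with 2 and 0 adjusted over the list alone). Of 55 ribosomal protein genes 6 rose and 1 fell (4 and 1 adjusted over the list alone, median -0.04 and 0.43 with spike-in centring, mean 0.02, camera direction up, adjusted p = 0.939), led by rplS (1.14 ± 0.24, adjusted p = 0.0249), rpsO (0.91 ± 0.19) and rpmA (0.68 ± 0.14). Without replicate A this list's median was -0.28 and it passed as lower (adjusted p = 0.0291). The fourth by p, rpsU (0.47 ± 0.04), was higher on 4 of 6 arrays, and rplS on 5 of 6.

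Of 21 competence genes 2 fell and 0 rose (12 and 0 adjusted over the list alone), namely the DNA uptake genes comGG (-1.15 ± 0.44, adjusted p = 0.0398) and comEC (-0.75 ± 0.25). The median was -0.60 (-0.13 with spike-in centring; camera, adjusted p = 4.84e-05, and adjusted p = 0.843 with an estimated correlation). For 53 motility genes the median was -0.22, with falls of tlpA (-1.09 ± 0.44), mcpB (-0.50 ± 0.11) and cheV (-0.47 ± 0.10, and 0.0053 with spike-in centring) and a rise of flgB (0.34 ± 0.07). That makes 3 falls and 1 rise (0 and 0 adjusted over the list alone; camera, adjusted p = 0.00798, and adjusted p = 0.843 with an estimated correlation), and the median was 0.25 with spike-in centring. The motility call was lost with that centring (adjusted p = 0.392), with median centring (0.0966), with the brightest probe (0.147) and on arrays with the depleted culture in Cy3 (median -0.060, adjusted p = 0.785). Among 57 genes of carbon catabolism repressed by CcpA, 11 fell and 2 rose (18 and 4 adjusted over the list alone), including falls of rocG (-0.77 ± 0.18, adjusted p = 0.0282), rbsA (-0.58 ± 0.18) and rbsD (-0.55 ± 0.13) and a rise of rocD (0.56 ± 0.14). The median was -0.17 (0.31 with spike-in centring; camera, adjusted p = 0.0218, adjusted p = 0.843 with an estimated correlation, adjusted p = 0.0664 with the slide as a random block, adjusted p = 0.0587 with the replicate block as random, and adjusted p = 0.0536 without replicate A). On arrays with the depleted culture in Cy3 camera's direction for this list turned to up (adjusted p = 0.986). With spike-in centring 16 genes of the CcpA list rose and 0 fell. In the arabinose list 1 of 11 genes, araA (-0.45 ± 0.11, adjusted p = 0.0402), fell, and araD had a ratio of -0.30, with spike-in values of 0.024 and 0.17 (0 and 0 adjusted over the list alone, and 6 at an unadjusted p under 0.05). Its median was -0.24 (0.23 with spike-in centring; camera, adjusted p = 0.00592, and adjusted p = 0.843 with an estimated correlation). The arabinose call was lost with the replicate block as random (adjusted p = 0.0913), on arrays with the depleted culture in Cy3 (0.112) and with spike-in centring (0.48).

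A further set of lists passed camera with few or 0 genes called, and their replicates stood apart. Respiration genes had a median of -0.89 over 33 genes with 0 calls in limma (0 and 0 adjusted over the list alone, and 2 at an unadjusted p under 0.05), made up of -2.20 in replicate A, -0.18 in B and -0.13 in C, the last of which were 0.18 and 0.18 with spike-in centring (camera, adjusted p = 0.00194, adjusted p = 0.843 with an estimated correlation, and adjusted p = 0.108 with the slide as a random block). The cytochrome oxidase genes ctaC and ctaE had ratios of -1.41 ± 1.05 and -1.21 ± 0.999. Of 26 genes behind S-box leaders 0 were called in limma (0 and 0 adjusted over the list alone, and 4 at an unadjusted p under 0.05), at medians of 0.15 in A, -0.60 in B and -0.94 in C, and metE had -1.06 ± 0.71 and yoaB -1.30 ± 0.9954. The list's median was -0.40 (0.07 with spike-in centring; camera, adjusted p = 0.0041, adjusted p = 0.843 with an estimated correlation, adjusted p = 0.0742 with the slide as a random block, adjusted p = 0.0936 on arrays with the depleted culture in Cy3, and adjusted p = 0.069 without replicate C). In the Fur regulon for iron uptake 1 of 30 genes was called, a rise of fecF (0.41 ± 0.11; 0 and 0 adjusted over the list alone), while the bacillibactin gene dhbE was at -2.53 in A, -0.42 in B and -3.32 in C. The median of that list was -0.40 (0.08 with spike-in centring; camera, adjusted p = 0.0288, adjusted p = 0.843 with an estimated correlation, adjusted p = 0.189 with the slide as a random block, and adjusted p = 0.205 without replicate A and 0.239 without C). The Fur call was also lost with the replicate block as random (0.0559), with median centring (0.0817), with the brightest probe (0.065) and on arrays with the depleted culture in Cy3 (0.246). Of 10 pyrimidine synthesis genes 0 were called in limma (0 and 0 adjusted over the list alone, and 5 at an unadjusted p under 0.05), with a median of 0.22, pyrC at 0.39 ± 0.17 and pyrR at 0.47 ± 0.23 (camera, adjusted p = 0.014, adjusted p = 0.843 with an estimated correlation, adjusted p = 0.187 with the slide as a random block, and adjusted p = 0.0866 without replicate C). The pyrimidine call was also lost with the replicate block as random (0.149), with spike-in centring (0.0677), on arrays with the depleted culture in Cy5 (0.945) and with replicate C from 1 array (0.0771). With spike-in centring, however, all 10 pyrimidine genes rose in limma, at a median of 0.70.

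**Figure D2:**
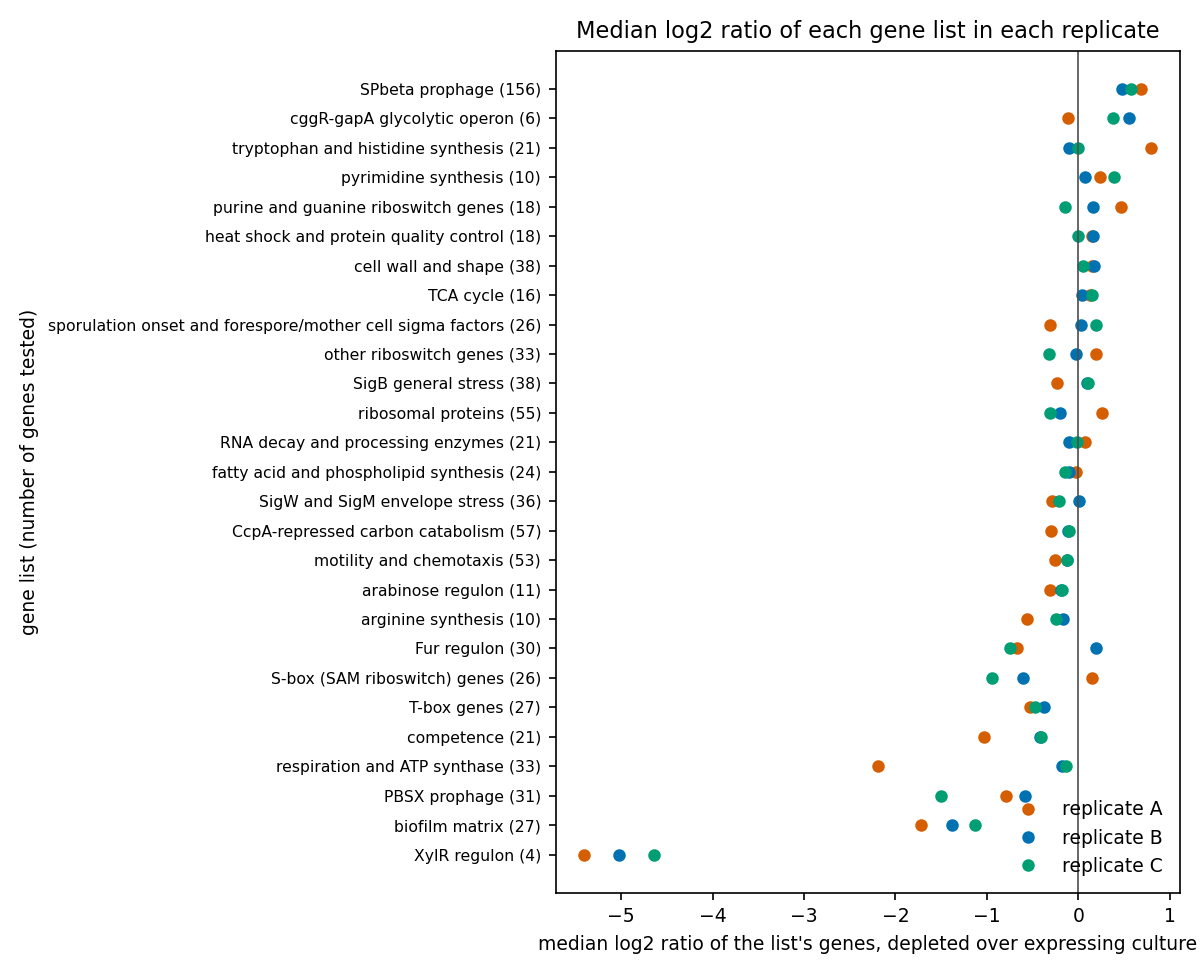
Median log2 ratio of depleted over expressing culture (x axis) over the tested genes of each of the 27 lists (y axis, number of genes in brackets), 1 point per replicate. The matrix genes lie between -1.72 and -1.13 in the 3 replicates, while the respiration genes lie at -2.20 in replicate A and above -0.2 in B and C.

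The remaining lists did not pass camera. Envelope stress genes under SigW and SigM had 2 rises and 5 falls of 36 (3 and 5 adjusted over the list alone, median -0.16 and 0.32 with spike-in centring, adjusted p = 0.0705, and 0.00545 without replicate B), among them a rise of relQ (0.77 ± 0.08) and falls of sppA (-1.06 ± 0.27), yteJ (-0.99 ± 0.22) and ydbT (-0.63 ± 0.24). The list of early sporulation had 6 rises and 2 falls of 26 (7 and 5 adjusted over the list alone, median 0.07, mean -0.01, adjusted p = 0.567), with rises of abrB (0.90 ± 0.23), spoIIR (0.45 ± 0.04) and spo0A (0.43 ± 0.07) and a fall of sdpA (-1.46 ± 0.58). With its brightest probe alone spoIIR was at -0.41. Heat shock genes had 3 rises and 0 falls of 18 (3 and 0 adjusted over the list alone; median 0.11, adjusted p = 0.251), namely ctsR (0.43 ± 0.05), mcsA (0.43 ± 0.06) and mcsB (0.42 ± 0.04). Lipid synthesis genes had 1 rise and 3 falls of 24 (1 and 3 adjusted over the list alone, median -0.13 and 0.34 with spike-in centring, adjusted p = 0.472), with acpA at -0.53 ± 0.11, fabHB at -0.48 ± 0.08, fabG at -0.38 ± 0.10 (0.090 with spike-in centring) and plsY at 0.33 ± 0.05. General stress genes under SigB had 1 rise, csbA (0.57 ± 0.22), and 1 fall, ctc (-0.45 ± 0.09, and 0.027 with spike-in centring), of 38 (0 and 0 adjusted over the list alone, median -0.01 and 0.46 with spike-in centring, adjusted p = 0.567). In 3 lists limma called 0 genes, also when adjusted over the list alone. Purine genes had a median of 0.17 over 18 genes, 5 of them at an unadjusted p under 0.05 (adjusted p = 0.109, and 0.0027 without replicate C), with nupG at 0.66 ± 0.30 and pbuG at 0.47 ± 0.22. Arginine genes had a median of -0.33 over 10 genes, 7 of them at an unadjusted p under 0.05 (0.15 with spike-in centring, adjusted p = 0.0672). In that list argB was at -0.42 ± 0.22 and argD at -0.41 ± 0.22, with spike-in values of 0.051 and 0.066. Citric acid cycle genes had a median of 0.07 over 16 genes, 4 of them at an unadjusted p under 0.05 (adjusted p = 0.472), with sdhA at 0.37 ± 0.14 and sdhC at 0.24 ± 0.06. In the 6 genes of the cggR-gapA operon 1 rose (1 adjusted over the list alone), the regulator gene cggR, 2.44-fold (1.29 ± 0.39, adjusted p = 0.0298), at a list median of 0.27 (adjusted p = 0.0893, and 0.00372 without replicate A).

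Within genes, probes of 1 annotated gene changed unequally in 87 of 3781 genes. Whether such probes lie on 1 transcript was not tested. In mpr the probe across the start codon was at -0.26 ± 0.21, while the other 5 lay between 1.07 and 1.14 (adjusted p = 1.45e-07 for the gene). The last probe of truB was at 0.43 ± 0.08 and its other 5 between -0.72 and -0.63 (adjusted p = 6.12e-07). The first probe of yetI (BSU07170) was at -0.22 ± 0.10 and its last 3 between 0.87 and 0.96 (adjusted p = 2.9e-05). In ywmC the last probe was at -0.53 ± 0.09 and the first 4 between 0.32 and 0.39 (adjusted p = 3.81e-05), and in spoIISA the first 2 probes were at 0.25 ± 0.10 and 0.15 ± 0.15 while the next 2 were at 1.33 ± 0.08 and 1.34 ± 0.09 (adjusted p = 5.87e-05). In mpr, yetI and spoIISA the probes nearer 0 were dimmer. Their log2 brightness was 9.26 in mpr, 8.87 in yetI and 7.69 and 8.30 in spoIISA, against 11.75 or more for the probes they are set against. Dim signal can pull a ratio towards 0, which was not tested here and would not by itself turn the sign, as in mpr and yetI. In the other genes named here the deviating probe was the brightest. Its brightness was 14.08 in truB (others 10.63 to 11.48), 14.74 in ywmC (first 4 probes 7.71 to 8.32) and 16.53 in rny (others 11.72 to 12.65). The lowest p of all belonged to rny (adjusted p = 2.59e-10), through its start-codon probe. In 29 of the 87 genes the most deviating probe spanned the start codon. The count was 35 without such probes, and 35, 17 and 9 without replicate A, B or C. It was 5 with spike-in centring, where the replicates' offsets enter the spread of each probe, 213 with the slide as a random block and 51 with the replicate block as random.

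Neighbouring genes on 1 strand changed unequally in 187 of 1923 pairs, with the downstream gene relatively higher in 85 and lower in 102. The pair of yhcC and yhcD, at the end of the yhbI cluster, cannot be read, because yhcD was not well above background in both cultures. Such dim signal can pull a ratio towards 0, which was not tested. In the xylose genes, xynB lay 1.503 above xynP (SE 0.04, adjusted p = 0.00197). The gene yloC lay 1.46 above tcaB (adjusted p = 0.00613), pabA for folate synthesis 1.34 above pabB (adjusted p = 0.0155), and qdoI 1.24 above qdoR (adjusted p = 0.0159). The difference of srtN minus mscY was -1.28 (adjusted p = 0.0184). A pair chosen after its values were seen was cggR and gapA, the glycolytic gene that follows it, whose difference was -1.01 (SE 0.05, adjusted p = 0.00613). It was -0.97 in replicate A, -0.93 in B and -1.12 in C, and gapA itself, at 0.28 ± 0.38, was not called. The count of pairs was 287 without replicate A and, with limma, 0 without B (361 at an unadjusted p under 0.05) and 0 without C (362). It was 471 with the slide as a random block and 339 with the replicate block as random.

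**Figure D3:**
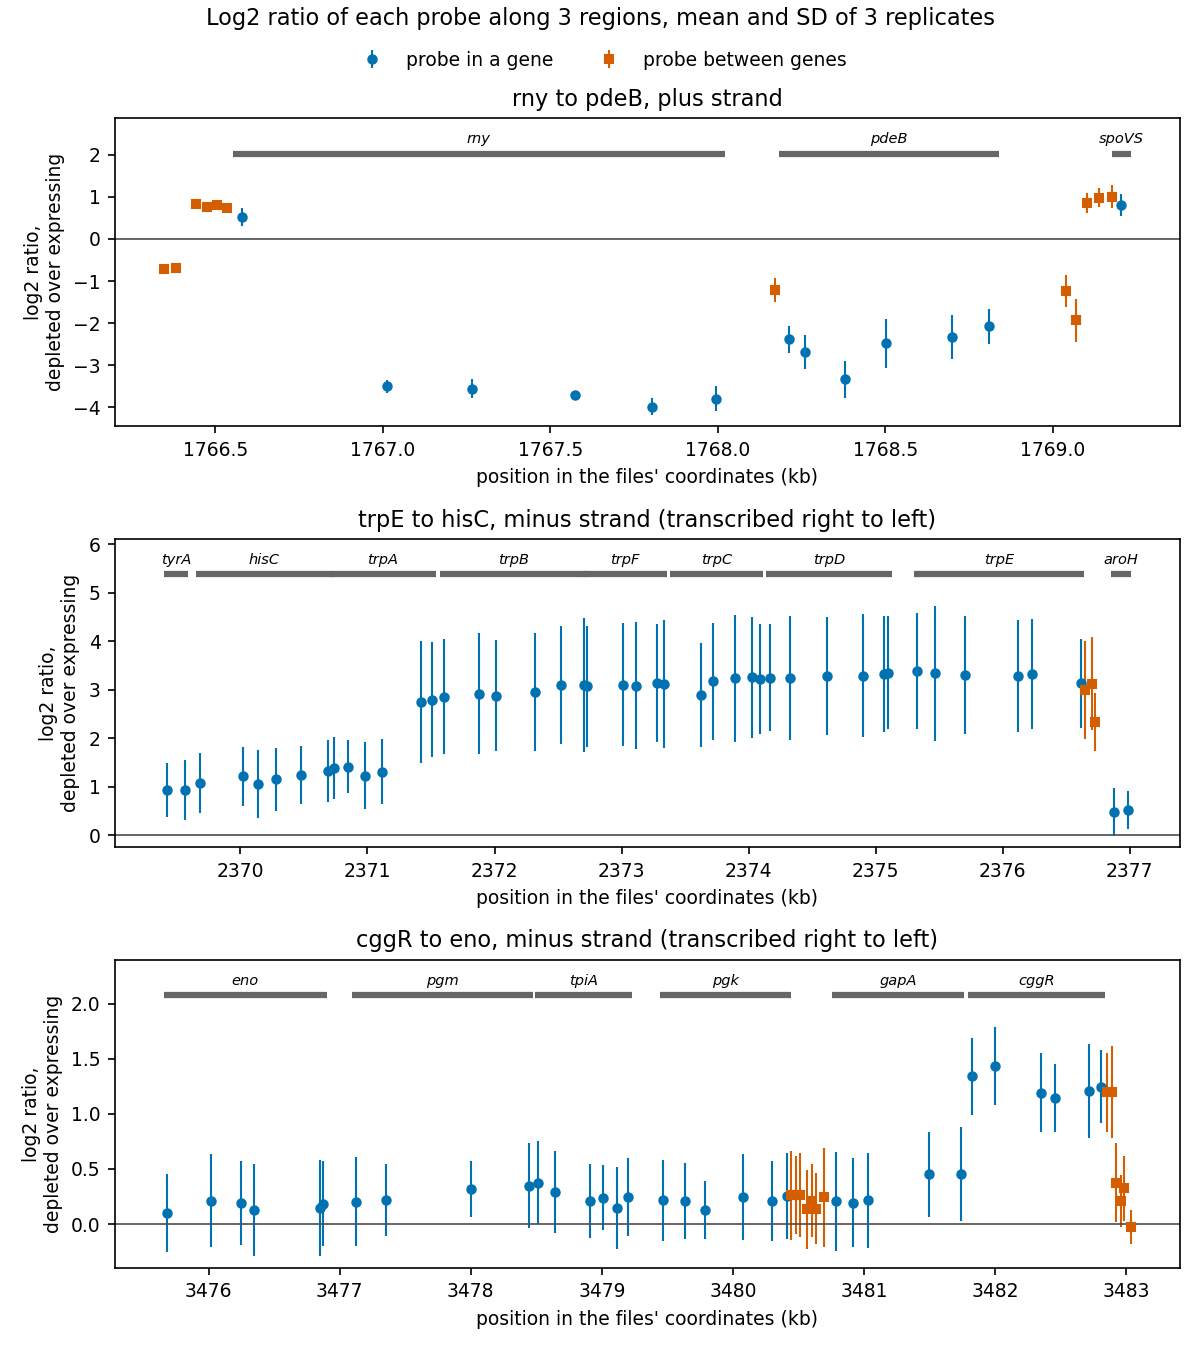
Log2 ratio of depleted over expressing culture (y axis, mean and SD of 3 replicates) of each probe against its position in the files' coordinates in kb (x axis), for rny and pdeB, the trp operon, and cggR to eno. Grey bars span the probes drawn for each gene. The start-codon probe of rny lies at 0.52 and the rest of the gene below -3.5, and cggR lies at 1.29 while gapA is at 0.28.

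Outside annotated genes, 318 features rose and 236 fell of 4223 tested, 56 of them at least 2-fold. Features with a gene of their own strand on both sides were called in 18.3% of 1398 cases (134 rises, 122 falls), those upstream of a gene only in 13.9% of 1041 (105 and 40), those downstream of a gene only in 12.3% of 324 (21 and 19), and those antisense to both neighbours in 7.22% of 1398 (51 and 50). These shares were not tested against each other. Whether a probe also took up signal from the opposite strand was not tested. The antisense calls are therefore not a count of changed antisense RNAs. Some features, chosen after their values were seen, are given here and are not a ranking. The region between xylA and xylB, from 1892458 to 1892581 on the plus strand, fell by 5.73 ± 0.42 (adjusted p = 0.0036). Its minus strand, antisense to both genes, was at -2.301 ± 0.449 (adjusted p = 0.0148). The log2 brightness was 7.413 there and 10.595 on the plus strand. Both strands also fell between xynB and xylR and rose between parC and ynfCn. How often the strands of a region moved together was not counted. The region upstream of trpE, from 2376621 to 2376822 on the minus strand, rose by 2.54 ± 0.47 (adjusted p = 0.0148). The region between gapB and speD rose by 1.78 ± 0.56 (adjusted p = 0.0215), the region upstream of fmnP, from 2409785 to 2409870, by 1.32 ± 0.16 (adjusted p = 0.0124), and the region between tasA and sipW fell by 1.84 ± 0.16 (adjusted p = 0.00785). With limma there were 472 rises and 530 falls without replicate A, 0 and 0 without B (873 at an unadjusted p under 0.05), and 1 and 2 without C (858). With spike-in centring they were 2027 and 53, with the slide as a random block 667 and 796, and with the replicate block as random 482 and 499.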

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

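The comparison of probes for genes without a locus tag with the negative controls was chosen after the arrays had been examined. The comparison of arrays was planned. On the array of replicate C with the depleted culture in Cy3, 92.1% of gene probes were well above background in the depleted culture and 89.4% in the expressing culture. The other 5 arrays lay between 98.8% and 99.9% and between 97.9% and 99.8%. This array stood far from the others in 2 of 5 measures compared over 6 arrays, and chance marks about 1 in 20 such groups. With replicate C taken from its other array alone, the rny value was -3.57. No biological explanation was tested.

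Probes for 16 genes listed without a locus tag, such as resistance markers and reporters, lay outside the comparisons. In 4 of these genes most probes were well above background in both cultures on all arrays. Their mean log2 brightness was 13.03 for the chloramphenicol resistance gene cat, 8.80 for luxB, 8.03 for tetR and 7.32 for aphA3, against 5.94 for the negative controls. The remaining genes lay between 6.02 and 7.42. The log2 ratio of cat was -0.08 ± 0.27 (SD, n = 3). The origin of these signals was not tested.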

How the results depend on the processing

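The alternatives without start-codon probes, without similar-site probes, with replicate C from 1 array and with all 10 spike-in RNAs were chosen after the data were seen, and the rest were planned. Of the comparisons of a summary with an alternative, 136 kept their direction and size, 63 counts moved by over 1.5 times, 1 was weaker and 1 reversed. Of those for single genes, lists and pairs, 2316 were the same, 83 stronger, 341 weaker and 40 reversed. Unless stated, the cause was not tested.

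Over the sets without 1 replicate, the ranges were 0 to 768 genes higher, 1 to 660 lower, 0 to 91 at least 2-fold higher, 1 to 75 at least 2-fold lower, 9 to 35 genes of unequal probes, 0 to 287 pairs, and 0 to 472 features higher and 0 to 530 lower. The rny value ranged from -3.72 to -3.55, with 12 to 15 lists called and a shift over the spike-in RNAs of 0.33 to 0.55. Fewer replicates leave less to estimate the spread from.

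With spike-in centring 1617 genes were higher and 83 lower (445 and 36 at least 2-fold), 2027 features higher and 53 lower, and 5 genes had unequal probes, where the offsets enter the residuals. The 553 genes shared with the calls above were counted over both directions. At a threshold of 0.01, 0 genes were higher and 3 lower (0 and 3 at least 2-fold). With the replicate block as random 683 genes were higher and 509 lower (107 and 115 at least 2-fold), 51 had unequal probes, 339 pairs differed, and 482 features were higher and 499 lower. With the slide as a random block 894 genes were higher and 738 lower, 9 lists passed, 213 genes had unequal probes, 471 pairs differed, and 667 features were higher and 796 lower. This slide fit counts the swapped arrays of 1 replicate as separate units. Arrays with the depleted culture in Cy5 gave 769 genes higher and 600 lower (160 and 146 at least 2-fold), 521 genes of unequal probes, 645 pairs, and 750 features higher and 340 lower. Those in Cy3 gave 232 genes of unequal probes, 496 pairs, and 270 features higher and 570 lower. On arrays of 1 orientation an effect of the dye cannot be told apart from depletion. Log2 ratios correlated at 0.86 between the Cy5 arrays of B and C and at 0.83 between their Cy3 arrays. Between swapped arrays the values were 0.85 in A, 0.495 in B and 0.75 in C. Replicate C from 1 array gave 38 genes of unequal probes, 55 pairs, and 254 features higher and 141 lower. Without start-codon probes 35 genes had unequal probes. Features higher and lower numbered 295 and 156 with the Agilent log ratio and 310 and 369 with median centring. Of 14 lists, 0 passed camera with an estimated correlation and 1, the XylR regulon, passed fry (adjusted p = 0.0304), which asks another question. Lists not called with all data also passed in places. These were SigW and SigM (adjusted p = 0.0401 on Cy5 arrays, 0.046 with replicate C from 1 array, 0.0498 with no replicate block), arginine (0.00412, 0.0245 and 0.0497 in the same settings), cggR-gapA (0.0352 with the Agilent log ratio, 0.0416 with spike-in centring), other riboswitches (0.000446 with spike-in centring, 0.0281 on Cy5 arrays), purines (0.0274 with the brightest probe, 0.00103 on Cy3 arrays) and tryptophan with histidine (0.0256 on Cy3 arrays).

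The brightest probe alone, which in rny spans the start codon, turned rny to 0.52 and spoIIR to -0.41. Spike-in centring, by its shift, turned araA to 0.024, araD to 0.17, argB to 0.051, argD to 0.066, cheV to 0.0053, ctc to 0.027 and fabG to 0.090. Cy3 arrays turned argB to 0.054, argD to 0.16, hisG to 0.29 and rpsU to -0.18, and Cy5 arrays sdhC to -0.064.

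Lists are given by median where camera's direction turned. With spike-in centring these were ribosomal proteins 0.43, RNA decay 0.43, SigB 0.46 and sporulation 0.54. On Cy3 arrays they were arginine 0.0023, CcpA -0.072, lipids 0.062 and ribosomal proteins -0.12, and on Cy5 arrays purines -0.085, RNA decay 0.070, the citric acid cycle -0.062 and tryptophan with histidine -0.18. Without 1 replicate the medians ranged from -0.28 (without A) to 0.040 for ribosomal proteins, from -0.069 to 0.090 (without A) for SigB, from -0.053 (without A) to 0.40 for tryptophan with histidine, from -0.043 to 0.012 for RNA decay, where it was -0.019 without B, and from -0.041 (without C) to 0.10 for sporulation. RNA decay was also at -0.015 with median centring, -0.090 with the brightest probe, -0.048 with the replicate block or fry and -0.056 with the slide block. Tryptophan with histidine was at 0.22 with the slide block and 0.23 with fry, sporulation at -0.0042 with the brightest probe, and ribosomal proteins at -0.091 without start-codon probes.

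The fit with no replicate block gave 351 genes higher and 182 lower and 16 lists, with rny at -3.66. Signal over background limits the weakest probes, as on the array where 89.4% were well above it.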

Other observations

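In the first pattern below the genes and all tests but that of the expressing culture were chosen after the result was seen, and so were the tests on genes under TRAP, since the rise of pabA had been seen. A set of 22 genes known to respond to low oxygen, among them cydA, narK and lctE, had a median log2 ratio of -5.33 in replicate A, -0.19 in B and -0.10 in C. The fall in B or C was at most 0.0354 of that in A, although rny fell alike in all 3, which argues against depletion of RNase Y as the cause for the set as a whole. In 4 members the fall was over 1 in B or C as well, namely lctE (-1.23 in B, -3.76 in C), ctaO (-1.42 and -1.13), lctP (-1.39 in B) and cydA (-1.15 in C), so a part of their fall outside A stays open. No member passed the test in limma (lowest adjusted p = 0.122). In replicate A rny was at -3.52 on the array where it fell less, which argues against swapped labels, and the gene set was at -5.28 on the array where it fell less, which argues against an artefact of 1 array. In separate channels the median level of these genes was 14.51 in the expressing culture of A, 8.87 in that of B and 8.59 in that of C, a gap of 5.65, while the depleted cultures lay at 8.00, 8.26 and 7.93. A state of the expressing culture of A, such as less oxygen at harvest, may thus lie behind the pattern, as a hypothesis found on the same data.

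The trp operon and its leader region (2.54 ± 0.47) are under the RNA-binding protein TRAP. Outside the operon, pabA was at 1.499 ± 0.22 (adjusted p = 0.0206), trpP at 0.49 ± 0.18 (adjusted p = 0.0486) and ycbK at -0.37 ± 0.24 (0.10 with spike-in centring). The median of these 3 averaged 0.49 over replicates (SD 0.18), but it is the value of trpP, and the 3 went both ways, so it decides nothing on stabilised trp mRNA with no change in TRAP. The arrays measured RNA, and neither free TRAP nor translation. Whether a fall in free TRAP would raise the RNA of these 3 genes was not tested. Of the 3, ycbK went the other way, and its direction turns with the scaling, so it decides nothing on such a fall. Both explanations stay open.

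Gene RNA lay above the spike-in RNAs by 0.47. If less spike-in RNA had been added to the depleted samples, stable RNA would lie above it as much. The test used 299 probes in 24 regions that hold rRNA and tRNA genes, on the brighter strand of each. They were not limited to the mature RNAs and had a median log2 brightness of 12.31, so how far they measure stable RNA is not known. Their median lay below that of genes by a mean difference of -0.23, with -0.10 in replicate A, -0.25 in B and -0.35 in C. As A stayed within the margin of 0.15 set for the test, a smaller addition of spike-in RNA cannot be told apart from a rise of mRNA.

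Turning the sign of 1 replicate at a time gives 4 patterns, too few for a share under 0.05. The real pattern gave 742 genes (highest other 0), 168 genes at least 2-fold (0), 14 lists (19), 87 genes of unequal probes (0), 187 pairs (0) and 554 features (0). As large a count came from 1 of the 4 patterns for each but the lists, where it came from 2.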
